A study of Rattus norvegicus and Mus musculus and Macaca mulatta with 84 samples.

How the data were processed

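Liver small RNA (53 libraries, prepared with the TriLink CleanTag kit per the labels) and polyadenylated RNA (31 libraries, Illumina TruSeq kit per the labels) were taken from 6 tables covering 18 groups. The small RNA tables hold reads per 1000000 mapped to miRNAs (RPM) as the authors deposited them. The libraries of each small RNA table sum to 1000000, so their sequencing depth is unknown, and the steps between low values did not give back whole reads. The RNA tables hold normalised counts made by the authors, a signal that is not whole numbers; their column sums, in units of 1000000, ran from 37.6 to 49.9 in rats and from 43.3 to 52.8 in mice. Per the submitters' processing notes STAR, Salmon and DESeq2 were used and the builds mm9, mm10, rn6 and hg19 were named; their versions and the role of each are not given in the sources used here. Monkey miRNAs carry human names in the deposited table. Small RNA features are miRNA forms, the canonical sequence and forms marked with a signed offset, listed once per locus, so a mature sequence encoded at several loci has several entries, which can hold the same reads. Of the tested forms with several loci 13 of 44 in UCD-T2DM rats, 10 of 44 in Zucker rats, 8 of 32 in mice and 6 of 71 in monkeys had identical values at all loci in every library, and the median gap between loci was 1.22% to 3.37% of the larger value. Forms with an offset are named by it, as marked +1 or -1.

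Groups were taken from the sample titles. Vehicle replicate 5 of the Zucker rats has a run name that says BT2; the title was followed, and the BT2 comparison without that library is given. Lanes were read from the run names. All 12 UCD-T2DM small RNA libraries ran in lane 3 and all 6 monkey libraries in lane 6; Zucker libraries were spread over lanes 1, 2 and 3 and mouse libraries over lanes 7 and 8. RNA tables have no lane in the labels. Within a group the lowest correlation of a library with its fellows ran from 0.917 to 0.988 across the tables, and no pair correlated above 0.997. Tables were normalised separately, so tests stayed within a table. All per-sample columns were used.

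Values were transformed to log2(value + 1) and features with a mean of at least 10 over a table were tested: 435 of 1076 forms in UCD-T2DM rats, 422 of 1204 in Zucker rats, 487 of 1158 in mice, 634 of 2629 in monkeys, 13640 of 32754 genes in rats and 14596 of 48440 genes in mice. limma 3.58.1 in R 4.3.3 fitted all groups of a table with a variance trend, without block or lane, for 14 comparisons; p-values are two-sided with Benjamini-Hochberg adjustment, called under 0.05. Count models were not run because the values are not counts. The miR-29 total, the sum of all loci of miR-29a-3p, miR-29b-3p and miR-29c-3p in canonical form, may therefore count reads of miR-29b-3p and, in rats, miR-29c-3p more than once; averaged over loci it was 4806 RPM in obese Zucker rats, for example, against 5312 summed. It was compared in 7 comparisons, and the members in 21, with two-sided exact permutation tests. Gene symbols are those paired with the gene identifiers in the tables; every identifier with a listed symbol entered its list. Genes that share reads with near-identical copies, such as haemoglobin, serum amyloid and cytochrome P450 genes, are uncertain, since the counting may split them.

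Before the data were examined 26 gene lists and 7 miRNA lists were fixed from textbook knowledge. They were fatty acid synthesis, cholesterol synthesis, fatty acid oxidation and ketogenesis, gluconeogenesis, insulin signalling, lipoproteins and lipid droplets, miR-29 matrix targets, miR-29 non-matrix targets, sirtuins, bile acids, acute phase, stress response, p53 response, interferon response, xenobiotic metabolism, circadian clock, proliferation, and markers of hepatocytes, stellate cells, Kupffer cells, sinusoidal endothelium, bile duct, lymphocytes and neutrophils, red blood cells, adipocytes and pancreatic acinar cells. The miRNA lists were the miR-29 family, liver metabolic, hepatocyte-enriched, stellate and fibroblast, blood cell, endothelial, and bile duct miRNAs. Their counts are counts of forms, and several forms can belong to the same mature miRNA. The metabolic list held 62 forms of 19 mature miRNAs in UCD-T2DM rats, 59 of 20 in Zucker rats, 46 of 20 in mice and 55 of 17 in monkeys. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Counts adjusted over the list alone use the p-values of that list only. Marker scores are means of log2 values, compared by exact permutation.

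Sirt1 was to be named always. Otherwise the rule named the 8 largest rises and falls among called genes with a symbol and a mean of at least 50 over the libraries compared, and up to 3 called members per list and direction, or 2 members as values where none was called. A list was described when camera called it or at least 3 members were called; both lipid synthesis lists and both miR-29 target lists were always described. Among miRNAs the rule named the 6 largest rises and falls with a mean of at least 100, the miR-29 members, up to 3 called members per list, and the 3 forms with the smallest p where none was called. Text examples are drawn from these; 1 of them is not reported here.

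The limma step was tested on simulated data with 40 changed features in each small RNA table and 200 changed genes in each RNA table. At a fold of 2 it recovered, in order of 2-week, 3-month and 3-month against 2-week comparisons, 95%, 80% and 100% of changed miRNAs in UCD-T2DM rats, and at a fold of 4 it recovered 100%, 95% and 100%. In Zucker rats it recovered, at folds of 2 and 4, 80% and 100% for obese and 95% and 100% for BT2; in mice 50% and 70% for ob/ob, 65% and 95% for streptozotocin, and 60% and 90% between them; in monkeys 0% and 70%. In the RNA tables it recovered 71% and 90% at 2 weeks, 80% and 96% at 3 months, 67% and 92% at 6 months, 71% and 91% between 6 months and 2 weeks, and 77% and 98% with LNA-29. Unchanged features called in the same simulations numbered, in the order given, 6, 0 and 1 in UCD-T2DM rats, 3 and 2 in Zucker rats, 0, 2 and 0 in mice, 0 in monkeys, and 11, 5, 8, 14 and 11 genes in the RNA tables.

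Alternatives were pseudocounts of 0.1 and 10, no minimum mean, a minimum of 100, median-of-ratios rescaling, a miR-29 total per 1000000 reads other than the most abundant miRNA, no variance trend, the compared groups alone, a replicate block, the lane as a covariate with and without a block, each lane alone, all shifted forms in the miR-29 total, and each library left out. After the data were seen, forms summed over loci, a miR-29 total averaged over loci, counts of forms per 1000000 reads other than the most abundant miRNA, and fits without 6 libraries in doubt were added. Those libraries were Zucker obese 2, BT2 5 and vehicle 5, streptozotocin 3, control 5 of the mice, and prediabetic 2 of the rat RNA table. They were chosen for low correlation with their own group or, for vehicle 5, for its run name. Up to 100 other splits of the libraries were drawn for each comparison with seed 29, permutation tests of correlations over 11 libraries used 100000 resamples while all others were exact, and shared controls were simulated 100 times. A test of genes with miR-29 seed sites was not run because no untranslated regions were used here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.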

Results

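Liver was profiled in 84 samples from rodent and monkey models of diabetes, obesity and diet, and from mice given a locked nucleic acid (LNA) against the microRNA miR-29. Small RNA was sequenced in 53 libraries held in 4 tables, and polyadenylated RNA in 31 libraries held in 2 tables. The UCD-T2DM rat, a model in which obesity and insulin resistance precede type 2 diabetes, gave small RNA libraries before diabetes (n = 3), after 2 weeks of diabetes (n = 6) and after 3 months (n = 3). It also gave RNA libraries before diabetes (n = 5) and after 2 weeks (n = 4), 3 months (n = 5) and 6 months (n = 6). The Zucker fatty rat model gave 5 small RNA libraries each from lean, obese, vehicle-treated and BT2-treated animals. Obese animals of this model carry a mutated leptin receptor, and lean animals serve as their controls. BT2 inhibits the kinase that restrains the breakdown of branched-chain amino acids. C57BL/6J mice gave 5 small RNA libraries each from controls, obese ob/ob mice and mice made diabetic with streptozotocin, which destroys the insulin-producing cells of the pancreas. Rhesus monkeys on fish oil or sunflower oil gave 3 small RNA libraries each, and mice gave 5 RNA libraries with LNA-29 and 6 controls.

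Small RNA values were reads per 1000000 mapped to miRNAs (RPM), summing to 1000000 in every library, and RNA values were normalised read counts whose sums, in units of 1000000, ran from 37.6 to 49.9 per rat library and from 43.3 to 52.8 per mouse library. The sequencing depth behind the small RNA values is unknown. Group values are means ± SD, and log2 changes are differences of mean log2(value + 1), which understate the change of features with low values. The labels name separate animals in the UCD-T2DM tables; in the others p-values measure the spread between these samples, which may be technical. Features were tested with limma and called at an adjusted p under 0.05.

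The first question was whether hepatic miR-29, a family that represses extracellular matrix genes, differs between diabetic and control livers. The sum of miR-29a-3p, miR-29b-3p and miR-29c-3p, of which miR-29a-3p made up the largest part, passed correction in none of the 7 planned comparisons. The smallest possible exact permutation p was 0.00794 for 5 against 5 libraries and 0.0119 for 6 against 3. A single comparison could therefore not pass correction over 7 totals, and the lack of a call does not show an unchanged total. In ob/ob mice the total was 3935 ± 924 RPM against 5213 ± 395 RPM in controls (log2 -0.44, n = 5 each), with a two-sided exact permutation p of 0.0238 and an adjusted p of 0.167 over the 7 totals. Within sequencing lane 7 the difference was -0.10, and within lane 8 it was -0.68. The total in streptozotocin diabetes was 5253 ± 553 RPM against the same controls (log2 0.01, exact permutation p = 0.921). It was 0.08 in lane 7 and -0.10 in lane 8, and -0.18 after median-of-ratios rescaling. The ob/ob and streptozotocin totals were -0.44 apart on the log2 scale (exact permutation p = 0.0317), in a test outside the 7 planned comparisons and without correction.

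Obese Zucker rats had a total of 5312 ± 621 RPM against 4448 ± 694 RPM in lean rats (log2 0.26, exact permutation p = 0.0873, adjusted p = 0.306, n = 5 each). This difference was 0.05 in lane 1 and 0.41 in lane 2, and it turned to -0.03 after rescaling. With BT2 the total was 4110.05 ± 771 RPM against 4129 ± 887 RPM with vehicle (log2 0.00, exact permutation p = 0.984, n = 5 each), and lane 3 alone gave -0.31. In UCD-T2DM rats the total was 6413 ± 986 RPM before diabetes (n = 3). It was 5735 ± 601 RPM at 2 weeks (n = 6, log2 -0.16, exact permutation p = 0.202) and 6813 ± 225 RPM at 3 months (n = 3, log2 0.10, exact permutation p = 0.8). Monkeys had 2095 ± 249 RPM on fish oil against 2925 ± 805 RPM on sunflower oil (n = 3 each, log2 -0.45, exact permutation p = 0.2). The smallest p that 3 against 3 libraries can give is 0.1.

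The family members differed in sign in ob/ob mice. Mature miR-29a-3p had 3306 ± 903 RPM against 4594 ± 404 RPM (log2 -0.52, exact permutation p = 0.0159), while the less abundant miR-29b-3p had 101 ± 18.8 RPM against 70.7 ± 12.5 RPM (log2 0.51, exact permutation p = 0.0238). In streptozotocin diabetes miR-29b-3p had 114 ± 22.7 RPM (log2 0.68, exact permutation p = 0.0159), and in obese Zucker rats 49.9 ± 14.4 RPM against 27.4 ± 9.71 RPM (log2 0.86, exact permutation p = 0.0238). None of the 21 member tests passed correction, and the smallest adjusted p was 0.125. With so few libraries a single member could not pass correction over 21 exact permutation tests, whatever its change. In the limma test over all miRNAs, miR-29a-3p fell in ob/ob mice (adjusted p = 0.0442), a call that ended after rescaling (adjusted p = 0.0536) and in 8 of 10 omissions of a single library, with the log2 change at -0.58 after rescaling and between -0.62 and -0.39 over the omissions.

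**Figure D1:**
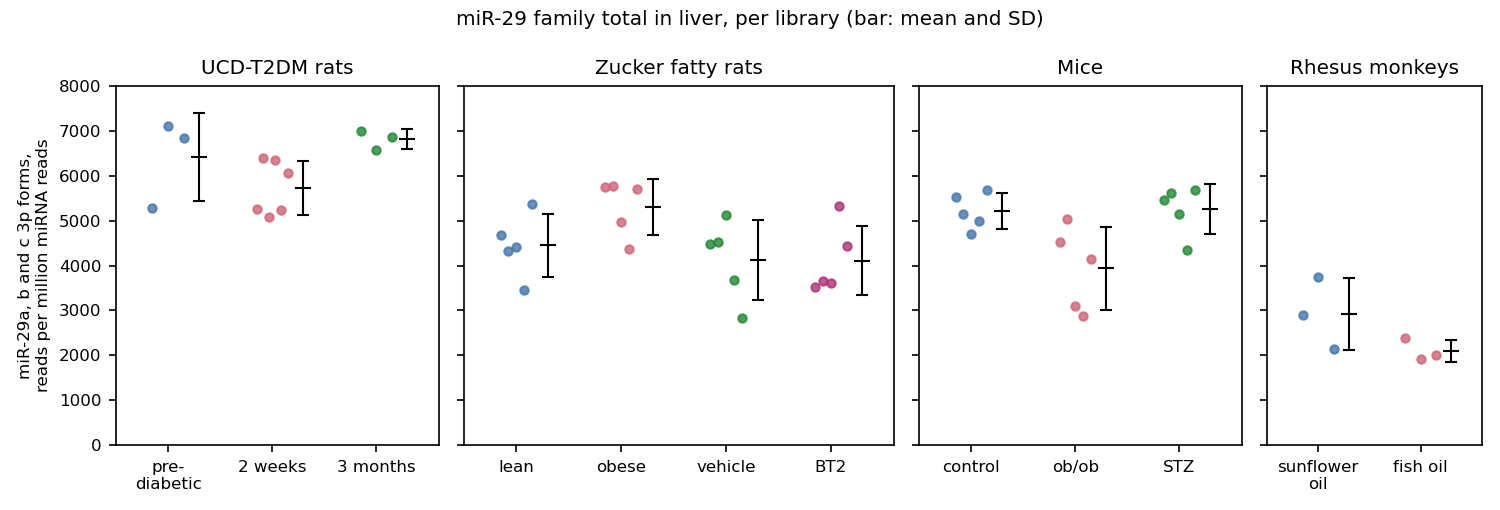
Summed RPM of miR-29a-3p, miR-29b-3p and miR-29c-3p in each small RNA library, by model and group, with group means and SD. The ob/ob libraries average 3935 RPM against 5213 RPM in controls, and the difference was -0.10 (log2) in lane 7 and -0.68 in lane 8.

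In UCD-T2DM rats the small RNA tables ask how hepatic miRNAs change from the prediabetic state into early and later diabetes. At 3 months of diabetes (n = 3) the islet miRNA miR-375-3p was at 433 ± 44.5 against 213 ± 27.4 RPM at 2 weeks (n = 6), and it rose by a log2 of 1.03 (SE 0.13, adjusted p = 0.00123). The proliferation-associated miR-221-3p rose from 2 weeks to 3 months (1189.9 ± 454 against 562 ± 75.2, log2 1.03, SE 0.19, adjusted p = 0.00375), as did miR-27b-3p (5360.0 ± 108 against 3544 ± 367 RPM, log2 0.60), miR-322-1-5p (log2 0.58) and miR-107-3p (log2 0.46). miR-29b-1-3p rose as well (37.5 ± 2.77 against 16.1 ± 3.45, log2 1.19, SE 0.19, adjusted p = 0.00154). Among the falls were miR-378a-3p (log2 -0.36, adjusted p = 0.00766), miR-378a-5p (log2 -0.44) and miR-378b (log2 -0.40), of which miR-378a arises from an intron of the mitochondrial regulator Ppargc1b.

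Of 435 forms tested, 109 were called from 2 weeks to 3 months, 87 up and 22 down. Rescaling moved the median by 0.15 and gave 108 calls, 51 up and 57 down, of which 73 were called either way; relative to that shift miR-375-3p differed by 0.88, miR-29b-1-3p by 1.04 and miR-378a-3p by -0.51. By list, 15 of 62 forms of liver metabolic miRNAs rose and 4 fell, 6 of 6 endothelial forms of miR-126a rose (miR-126a-3p log2 0.41), 3 of 13 miR-29 forms rose, and 1 hepatocyte-enriched form of 24 rose and 2 fell. Adjusted over the list alone the counts were, in that order, 21 up and 7 down, 6 up, 7 up, and 0. The median of the metabolic list was 0.13 and turned to -0.02 after rescaling, and that of the hepatocyte-enriched list turned from 0.04 to -0.11. Forms of the stellate, blood and bile duct lists were not called. Each 3-month library carried part of the count: 51 forms were called without 3-month 1, 50 without 3-month 2 and 52 without 3-month 3.

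From prediabetes to 3 months (n = 3 each), 5 forms were called, and all are named here after their values were seen. The canonical miR-221-3p (1189.9 ± 454 against 505 ± 93.6, log2 1.18, SE 0.22, adjusted p = 0.0265) and its form marked +1 (log2 1.31) rose, as did miR-185-5p (61.2 ± 0.309 against 38.3 ± 7.77 RPM, log2 0.68); miR-672-5p (7.76 ± 1.38 against 17.2 ± 4.01 RPM, log2 -1.05) and miR-193a-5p (26.7 ± 4.12 against 40.8 ± 1.58 RPM, log2 -0.60) fell. The calls of miR-221-3p and its +1 form ended without prediabetic 1 or prediabetic 3 (adjusted p up to 0.102), and those of miR-185-5p, miR-672-5p and miR-193a-5p in 5 of 6 omissions each (adjusted p up to 0.191). Rescaling gave 21 calls, values per 1000000 reads other than miR-122-5p gave 28 (11 up, 17 down), and no form was called without prediabetic 3, 1 without prediabetic 1, 2 without 3-month 3 and 3 without any other library. miR-29b-1-3p was at a log2 of 0.79 (adjusted p = 0.0840, and 0.0379 after rescaling), miR-29a-3p at 0.09 and miR-29c-1-3p at 0.07. None of the 7 lists had a called form there; adjusted over the list alone, 3 miR-29 and 2 metabolic forms rose and 2 bile duct forms fell. At 2 weeks against prediabetes limma called 0 forms, with 44 at an unadjusted p under 0.05. The smallest p belonged to miR-375-3p and its shifted forms: canonical miR-375-3p had 213 ± 27.4 against 305 ± 53.6 RPM (log2 -0.52, adjusted p = 0.366), and the form marked -1 a log2 of -0.68 (adjusted p = 0.139). miR-29a-3p, miR-29b-1-3p and miR-29c-1-3p were at -0.12, -0.40 and -0.26 at 2 weeks.

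Obese and lean Zucker rats (n = 5 each) were compared to read the effect of leptin receptor loss and obesity. Vehicle-treated Zucker fatty rats were not tested against lean rats. Their miR-802-5p ran from 698 to 1512 RPM, against 1253 to 2410 in obese and 800 to 1190 in lean liver. Their miR-34a-5p ran from 566 to 1147 RPM, against 686 to 1363 in obese and 190 to 608 in lean liver. Their mean miR-132-3p, given below with BT2, was near that of lean liver and far below that of obese liver. Among forms with a mean of at least 100 RPM, the largest rises in obese liver were those of miR-182 (669 ± 140.5 against 114 ± 30.2, log2 2.56, SE 0.24, adjusted p = 1.3e-07), miR-155-5p of activated leukocytes (210.2 ± 37.8 against 55.4 ± 12.9 RPM, log2 1.92) and the p53-responsive miR-34a-5p (1105 ± 269.5 against 349 ± 199, log2 1.80, SE 0.31, adjusted p = 0.000252). Rises were also called for miR-132-3p (39.2 ± 15.3 against 8.30 ± 1.26 RPM, log2 2.06), miR-802-3p, a miRNA linked to obesity-associated insulin resistance (409.6 ± 41.7 against 239.5 ± 31.7 RPM, log2 0.78), miR-200c-3p (log2 1.13), miR-322-1-5p (log2 1.21) and miR-450a-5p (log2 1.19). The hepatocyte miRNA miR-122-5p, which held 43.1% ± 5.81 of all reads in obese and 50.7% ± 4.09 in lean liver, fell (log2 -0.24, adjusted p = 0.0223; relative to the shift given next -0.53). That call ended in 5 of 10 omissions of a library (adjusted p up to 0.0713) and without the libraries in doubt. The difference in the share of reads held by miR-122-5p did not reach the threshold (exact permutation p = 0.0794, adjusted p = 0.3 over the small RNA comparisons).

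In all, 163 of 422 forms were called in obese rats, 150 up and 13 down. Rescaling moved the median by 0.29 and gave 120 calls, 60 up and 60 down, of which 73 were called either way, and values per 1000000 reads other than miR-122-5p gave 108 calls, 82 up and 26 down; relative to the shift of 0.29 the changes were 2.27 for miR-182, 1.63 for miR-155-5p, 1.51 for miR-34a-5p and 0.49 for miR-802-3p. The metabolic list had 30 rises and 7 falls of 59 forms (37 and 9 adjusted over the list alone), the miR-29 family 4 rises of 11, and the hepatocyte-enriched list 6 falls of 24 (5 alone). These forms belong to 20, 5 and 6 mature miRNAs, and the 6 endothelial forms to 2. Stellate and fibroblast forms rose in 5 of 11 (miR-199a-5p log2 1.38, miR-214-3p log2 1.18), blood cell forms in 3 of 8 (miR-223-3p of neutrophils log2 1.11), endothelial forms in 5 of 6 (miR-126a-3p log2 0.56) and bile duct forms in 2 of 7 (miR-141-3p log2 1.01). Rescaling lowered the list medians from 0.61 to 0.33 (stellate), 0.81 to 0.53 (blood cell), 0.55 to 0.26 (endothelial), 0.58 to 0.30 (bile duct) and 0.47 to 0.19 (metabolic), and the calls of miR-126a-3p and miR-141-3p ended with it. They also ended without obese 5, that of miR-126a-3p without obese 2, and that of miR-141-3p without lean 1 or 2 (adjusted p up to 0.0713). After rescaling miR-29a-3p and miR-29c-1-3p turned to -0.03 and -0.06, while miR-29b-1-3p (0.84, adjusted p = 0.0176) stood at 0.57 (adjusted p = 0.0770). Within lane 1 limma called 39 forms (32 up, 7 down) and within lane 2 it called 29, all up; lane 3 held 1 library of each group. All 163 forms called over the pooled lanes had the same direction in each of the 3 lanes, as had 69.2% of all forms tested.

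BT2 against vehicle (n = 5 each) tested the drug in Zucker fatty rat liver. BT2 raised miR-132-3p (17.6 ± 3.07 against 7.63 ± 1.05, log2 1.10, SE 0.18, adjusted p = 0.00392), higher in 5 of 5 treated livers than in any vehicle liver, and miR-92a-1-5p (22.3 ± 3.12 against 12.2 ± 3.31, log2 0.85, SE 0.18, adjusted p = 0.0224), which is named after its values were seen. These were the 2 forms called of 422, and the call of miR-92a-1-5p ended in 7 of 10 omissions of a library (adjusted p up to 0.0928) and after rescaling (adjusted p = 0.0579). miR-132-3p is transcribed with miR-212 under the control of CREB, the cAMP-responsive factor. The metabolic list had 1 rise of 59 forms, and none of the other lists had a called form; adjusted over the list alone the metabolic count was also 1. The member values were 0.07 for miR-29a-3p, -0.41 for miR-29b-1-3p and -0.35 for miR-29c-1-3p. Without vehicle 5, whose run name differs from its title, 2 forms were called, miR-132-3p stood at a log2 of 1.15 (adjusted p = 0.00357) and the miR-29 total at -0.12 (exact permutation p = 0.437). After rescaling 1 form was called, and within lane 3 none; lanes 1 and 2 held 1 BT2 library each.

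Genetic obesity (ob/ob) and insulin-deficient diabetes were set against the same 5 control mice. In ob/ob liver (n = 5) miR-802-5p, which was at 1138 ± 116 against 161 ± 56.5 RPM, rose by a log2 of 2.87 (SE 0.21, adjusted p = 6.0e-08), and miR-34a-5p rose as well (174 ± 19.9 against 34.4 ± 2.88, log2 2.31, SE 0.14, adjusted p = 1.0e-08). Rises were also called for miR-205-5p (log2 4.25), miR-802-3p (log2 3.12) and miR-676-3p (2274 ± 389 against 333 ± 140.2 RPM, log2 2.86), and miR-107-3p, another regulator of insulin sensitivity, rose by 1.61. The liver miRNA miR-1948-3p fell (165 ± 55.3 against 859 ± 74.9, log2 -2.43, SE 0.25, adjusted p = 3.5e-06), as did miR-125a-5p (log2 -1.87) and miR-146a-5p (log2 -1.63), a feedback inhibitor of innate immune signalling. In all, 119 of 487 forms were called, 72 up and 47 down.

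The metabolic list had 10 rises and 1 fall of 46 forms in ob/ob liver. In other lists the called forms fell: 4 of 22 stellate and fibroblast forms (miR-145-3p log2 -1.53), 5 of 18 blood cell forms (miR-142-5p log2 -1.12), 1 of 19 hepatocyte-enriched forms, 1 of 5 endothelial forms (miR-126-3p marked +1, log2 -0.55), 1 of 6 bile duct forms (miR-200b-3p log2 -1.11) and 1 of 10 miR-29 forms. Adjusted over the list alone the stellate count was 1, the endothelial count 0, and the miR-29 list had 2 rises and 1 fall. Within lane 7 limma called 32 forms and within lane 8 it called 59, and 119 of 119 forms called over both lanes had the same direction in each, as had 77.0% of all forms tested. The form of miR-126-3p marked +1 was not called after rescaling (adjusted p = 0.0586) or in 8 of 10 omissions of a library, and the call of miR-200b-3p ended in 5 of 10 (adjusted p up to 0.0846). The count was 71 without ob/ob 3 and 76 without control 1.

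In streptozotocin diabetes (n = 5) the largest rise among forms with a mean of at least 100 RPM was that of miR-34a-5p (573 ± 77.2 against 34.4 ± 2.88, log2 4.01, SE 0.14, adjusted p = 6.7e-12), followed by miR-375-3p (191 ± 132 against 18.7 ± 6.22 RPM, log2 3.09), miR-802-5p (log2 2.50) and miR-802-3p (log2 1.95). miR-1948-3p fell (log2 -1.62, SE 0.25, adjusted p = 0.000566). Of 487 forms 43 were called, 36 up and 7 down. Rescaling moved the median by 0.18 and gave 35 calls, 26 up and 9 down, of which 33 were called either way; relative to it miR-34a-5p differed by 3.83 and miR-1948-3p by -1.80. The metabolic list had 7 rises of 46 forms and the miR-29 list 2 of 10, or 3 adjusted over the list alone; the remaining lists had none. The rise of miR-29b-1-3p (0.70, adjusted p = 0.0277) was not called after rescaling (adjusted p = 0.147) or in 7 of 10 omissions of a library. Lane 7 alone gave 57 calls and lane 8 alone 16, with 43 of 43 forms called over both lanes in the same direction in each, as were 72.5% of all forms tested. The count was 74 without control 5, and fell to 22 without control 1, 23 without control 2 or streptozotocin 4, and 24 without control 3.

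Because the controls were shared, the models were also compared directly. ob/ob liver exceeded streptozotocin liver in miR-205-5p (log2 2.83), miR-676-3p (log2 2.30, adjusted p = 5.4e-05), miR-802-3p (log2 1.17) and miR-107-3p (log2 1.16), while miR-34a-5p (log2 -1.71, SE 0.14, adjusted p = 6.5e-07) and miR-92b-3p (log2 -1.95) were lower. miR-375-3p was lower in ob/ob liver over both lanes (log2 -2.04) but stood at 0.04 within lane 7, and its call ended in 9 of 10 omissions of a library (adjusted p up to 0.106) and without the libraries in doubt. Of 487 forms 65 differed, 33 higher and 32 lower; rescaling moved the median by -0.11 and gave 55 calls, 39 higher and 16 lower, 48 of them called either way. The metabolic list had 5 higher and 3 lower forms and the blood cell list 4 lower (6 adjusted over the list alone), among them miR-142-3p (log2 -0.74, a call that ended after rescaling and in 7 of 10 omissions); the remaining lists had none. Only 7 forms were called within lane 7 and 5 within lane 8, and the count ranged from 19 without ob/ob 3 to 80 over the omissions of a single library (22 without ob/ob 5, 34 without streptozotocin 1 or 2, 37 without ob/ob 2 or streptozotocin 3, 42 without ob/ob 4).

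The changes of both mouse models correlated across forms, which are not independent replicates, with r = 0.71, where unchanged groups simulated against the same controls gave 0.43. Their covariance was 0.587 against a simulated 0.0846. Rises shared by both models numbered 18, against 5.32 for independent lists, and shared falls 7, against 0.676. With the controls split between the models r was 0.46 and 0.57, 9 and 8 rises were shared, and 1 and 3 falls.

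**Figure D2:**
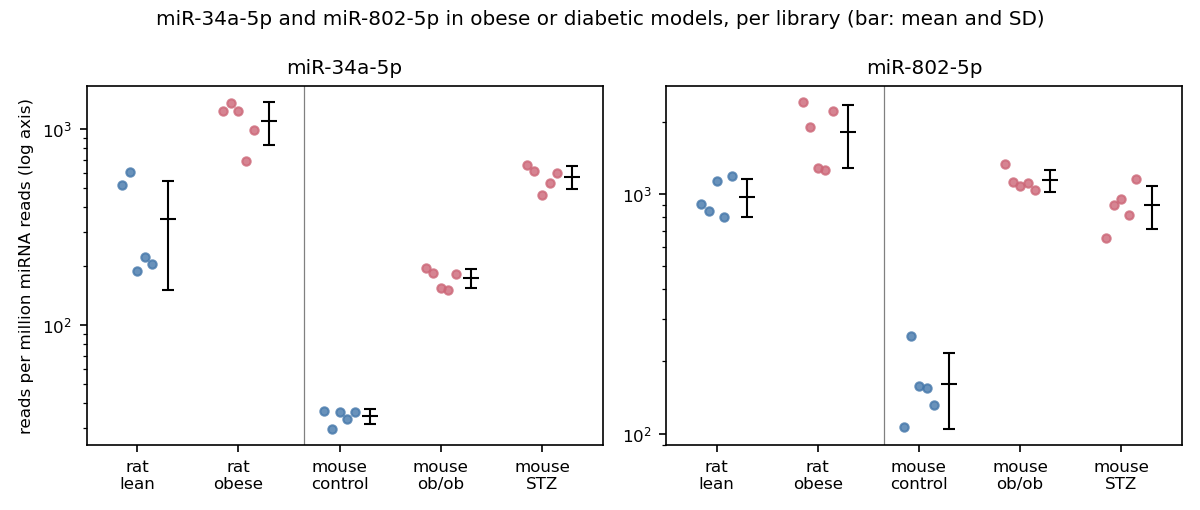
RPM of miR-34a-5p and miR-802-5p in each library on a log axis, with group means. In streptozotocin liver miR-34a-5p was at 573 ± 77.2 against 34.4 ± 2.88 RPM in controls, and in ob/ob liver miR-802-5p was at 1138 ± 116 against 161 ± 56.5 RPM.

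Monkeys on fish oil were compared with those on sunflower oil (n = 3 each) to read the effect of marine fatty acids. No form of 634 was called by limma, with 102 at an unadjusted p under 0.05. The smallest p belonged to miR-4443 (21.7 ± 2.03 against 3.74 ± 0.662, log2 2.27, SE 0.43, adjusted p = 0.0590), miR-744-5p (186 ± 36.0 against 63.7 ± 10.4 RPM, log2 1.53, adjusted p = 0.0791) and miR-885-3p (log2 1.69, adjusted p = 0.108). No form of any of the 7 lists was called. Rescaling moved the median by 0.17. Relative to it miR-29a-3p differed by -0.55. Without control 1, 3 forms were called, and 1 without control 2 or fish oil 3.

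The RNA tables of UCD-T2DM rats cover the same disease to 6 months. For RNA and small RNA alike, each group held different rats. The ages of these rats are not given here, so diabetes and its duration cannot be told apart from age. At 2 weeks of diabetes (n = 4) no gene of 13640 was called against prediabetic liver (n = 5) by limma, with 1077 at an unadjusted p under 0.05. Normalised counts of Scd, the stearoyl-CoA desaturase of fatty acid synthesis, were 14895 ± 8383 against 62742 ± 30566 (log2 -2.10, adjusted p = 0.592), and those of the cholesterol enzyme gene Sqle differed by a log2 of 1.21. Camera placed lists of fatty acid synthesis (adjusted p = 2.6e-05), fatty acid oxidation and ketogenesis (1.7e-12), lipoproteins and lipid droplets (2.2e-05), gluconeogenesis (0.0266) and hepatocyte markers (0.0266) below other genes. It placed cholesterol synthesis (0.0285), miR-29 matrix targets (0.0023) and stellate cell markers (0.0186) above them. With an estimated correlation the adjusted p = 0.429, 0.198, 0.134, 0.548 and 0.429 for the former and 0.818, 0.548 and 0.429 for the latter. Adjusted over the list alone, 5 oxidation genes, 3 lipoprotein genes and 1 gluconeogenesis gene fell, and 1 gene each of the matrix, stellate and xenobiotic lists rose, among them the stellate gene Lrat (1087 ± 259 against 626 ± 92.1). Without 2-week 2, or without 2-week 3, 3 genes were called.

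At 3 months of diabetes (n = 5 in each group) the lipogenic desaturase Scd fell to 192 ± 284 against 62742 ± 30566 normalised counts (log2 -9.10, SE 0.90, adjusted p = 5.0e-06). The lipid droplet lipases Pnpla3 (log2 -3.70) and Pnpla5 (log2 -5.92) and the lipogenic regulator Thrsp (log2 -2.41) fell with it. The insulin-repressed binding protein gene Igfbp2 rose (10849 ± 6595 against 242 ± 177, log2 5.43, SE 0.66, adjusted p = 6.6e-05), as did Ppp2r2b (log2 4.44), Tgm1 (log2 3.64) and Krt23 (log2 3.27), while Sdr16c6 (log2 -8.17), Ltc4s (log2 -4.93) and Stac3 (log2 -4.47) fell. The acute phase gene Lcn2 rose (log2 4.07, adjusted p = 0.0261) with 3-month 1 at 35265 counts. Its call ended without 3-month 1, prediabetic 4 or prediabetic 5 (adjusted p up to 0.0777). In all, 2248 of 13640 genes were called, 1058 up and 1190 down, and 1456 without 3-month 1.

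Lipid synthesis split by pathway at 3 months. Of 20 fatty acid synthesis genes 10 fell and 0 rose (13 falls adjusted over the list alone; camera adjusted p = 4.6e-07; adjusted p = 0.338 with an estimated correlation). Of 25 cholesterol synthesis genes 11 rose and 0 fell (11 alone; adjusted p = 4.6e-05; adjusted p = 0.473 with an estimated correlation), including squalene epoxidase Sqle (2144 ± 947 against 410.5 ± 176, log2 2.37, SE 0.37, adjusted p = 0.000534), Idi1 (log2 2.02) and Fdft1 (log2 0.88). Fatty acid oxidation and ketogenesis fell in 15 of 25 genes (16 alone; adjusted p = 4.6e-07; adjusted p = 0.378 with an estimated correlation). Among them were the long-chain acyl-CoA dehydrogenase gene Acadl (14404 ± 2421 against 21889.7 ± 3025, log2 -0.61, SE 0.14, adjusted p = 0.00851) and the peroxisomal enzyme gene Ehhadh (log2 -0.84). Lipoprotein and lipid droplet genes fell in 9 of 20 (9 falls and 1 rise alone; adjusted p = 0.000539; adjusted p = 0.252 with an estimated correlation), including hepatic lipase Lipc (log2 -1.10) and Apoa4 (log2 -1.76).

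Carbohydrate, insulin and bile acid genes moved both ways at 3 months and their lists were not called. Gluconeogenesis had 1 rise and 4 falls of 12 (1 and 5 adjusted over the list alone), with Pc at a log2 of -0.76. The insulin list had 3 rises, namely Trib3 (log2 1.51), Irs2 (log2 1.18) and the insulin-repressed Igfbp1 (log2 2.32), and 4 falls, among them Igf1 (log2 -0.66) and the fructose kinase Khk (log2 -0.79). Bile acid genes had 3 rises and 1 fall of 10 (4 and 1 alone): the export pump Abcb11 (log2 0.80) rose and the 12-alpha-hydroxylase Cyp8b1 (log2 -1.94) fell. Xenobiotic genes had 4 rises and 2 falls of 10 (4 and 3 alone), with the transporter Abcc3 at a log2 of 3.13 and Cyp2b2 at -3.33. Of 11 p53 response genes 3 fell (4 alone; camera adjusted p = 0.0509), including Cdkn1a (log2 -2.21). The stress response list had 2 rises and 1 fall of 15, interferon and clock lists 1 fall each, and the 14 proliferation genes and 6 sirtuins had none.

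Markers of non-parenchymal cells moved with these pathways at 3 months. Kupffer cell and macrophage markers rose in 9 of 10 genes (10 adjusted over the list alone; camera adjusted p = 3.1e-06; adjusted p = 0.44 with an estimated correlation), among them Cd5l (5202 ± 2091 against 1857 ± 352, log2 1.40, SE 0.32, adjusted p = 0.00686) and the complement receptor Vsig4 (log2 1.05). Stellate cell markers rose in 7 of 12 (adjusted p = 2.0e-05; adjusted p = 0.24 with an estimated correlation), among them decorin, Dcn (log2 2.08), and miR-29 matrix targets in 7 of 18 (11 alone; adjusted p = 0.00293; adjusted p = 0.473 with an estimated correlation), among them Col5a2 (log2 0.81), Col4a1 (log2 0.72) and Fbn1 (log2 0.71). Lymphocyte and neutrophil markers rose in 3 of 10 (adjusted p = 0.0322; S100a9 log2 3.22), acute phase genes in 3 of 14 (7 alone; adjusted p = 0.012) and sinusoidal endothelial markers in 1 of 9 (4 alone; adjusted p = 0.0179), each with an adjusted p = 0.473 with an estimated correlation. The mean log2 of stellate markers was 0.82 higher (SE 0.16, exact permutation p = 0.00794) and that of hepatocyte markers differed by -0.22 (exact permutation p = 0.0159). Bile duct and red blood cell lists had 1 rise each, hepatocyte markers 2 falls of 9, and the 2 adipocyte genes none. Of 23 miR-29 non-matrix targets 2 fell and 0 rose (camera adjusted p = 0.856).

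At 6 months (n = 6) Scd was again far below prediabetic liver (n = 5), at 463 ± 904 against 62742 ± 30566 counts (log2 -8.65, SE 0.86, adjusted p = 5.1e-06) and Igfbp2 rose to 17651 ± 10571 against 242 ± 177 (log2 6.33). The activin antagonist Fst (log2 6.01), the transcription factor Foxq1 (log2 5.34) and the procollagen processing enhancer Pcolce (4705 ± 3331 against 164 ± 43.5, log2 4.36) rose, as did Lcn2 (log2 5.07), Crtac1 (log2 4.78), Rnf186 (log2 4.90) and the potassium channel gene Kcnma1 (log2 4.75). Sdr16c6 (log2 -8.37), Pnpla5 (log2 -5.37), Stac3 (log2 -4.60) and Paqr9 (log2 -4.18) fell. In all, 2875 genes were called, 1505 up and 1370 down.

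At 6 months fatty acid synthesis fell in 15 of 20 genes (16 adjusted over the list alone; camera adjusted p = 1.0e-08; adjusted p = 0.27 with an estimated correlation), including the elongase Elovl5 (log2 -1.91). Cholesterol synthesis rose in 13 of 25 (adjusted p = 3.3e-06; adjusted p = 0.403 with an estimated correlation), including Sqle (log2 2.49) and the regulator Srebf2 (log2 0.83). Fatty acid oxidation fell in 14 of 25 (20 alone; adjusted p = 4.5e-09; adjusted p = 0.27 with an estimated correlation), including Bdh1 (log2 -1.53). Lipoprotein and lipid droplet genes had 11 falls and 2 rises of 20 (13 and 2 alone; adjusted p = 3.8e-05; adjusted p = 0.205 with an estimated correlation), with Lipc down (log2 -1.38) and lipoprotein lipase Lpl up (log2 1.57).

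Lists of Kupffer, acute phase, stellate, bile duct, and lymphocyte and neutrophil genes lay higher by camera at 6 months, with part of their members called. Kupffer markers rose in 9 of 10 (10 adjusted over the list alone; adjusted p = 6.8e-07; adjusted p = 0.359 with an estimated correlation), including Cd5l (log2 1.55) and C1qc (log2 1.00). Acute phase genes rose in 6 of 14 (10 alone; adjusted p = 0.000181; adjusted p = 0.359 with an estimated correlation), including fibrinogen Fgb (593135 ± 228821 against 223700.0 ± 46903, log2 1.33, SE 0.27, adjusted p = 0.00202) and Il1b (log2 1.70). Stellate markers rose in 5 of 12 (7 alone; adjusted p = 0.0018; adjusted p = 0.27 with an estimated correlation). Bile duct markers rose in 2 of 6 (3 alone; adjusted p = 0.0121) and lymphocyte and neutrophil markers in 4 of 10 (adjusted p = 0.0073), both with an adjusted p = 0.403 with an estimated correlation; Krt19 (log2 2.01), Sox9 (log2 1.86) and S100a9 (log2 2.91) were among them. The mean log2 of Kupffer markers was 1.11 higher (adjusted p = 0.0195 over the marker lists, exact permutation test). That of hepatocyte markers differed by 0.08 (exact permutation p = 0.381), with Fgb, which rose and is also on the acute phase list, among the 9 members.

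The other 16 lists tested were not called at 6 months. miR-29 matrix targets had 3 rises and 1 fall of 18 (4 and 2 adjusted over the list alone; adjusted p = 0.135), with the collagen processing protease Adamts2 up (log2 0.92; adjusted p = 0.0663 without prediabetic 4) and lysyl oxidase Lox down (log2 -2.50; its call ended in 9 of 11 omissions of a library). Non-matrix targets had 2 rises and 4 falls of 23 (adjusted p = 0.437). Bile acid genes had 5 rises and 1 fall of 10 (5 and 2 alone), xenobiotic genes 5 and 3 of 10, stress response genes 4 and 1 of 15 with Atf3 up (log2 2.96), insulin genes 3 and 4 of 14 (4 and 6 alone), gluconeogenesis genes 1 and 2 of 12, and p53 response genes 1 and 4 of 11 with Btg2 up (log2 1.34). Hepatocyte markers had 2 rises and 1 fall of 9, transthyretin Ttr being the fall (log2 -1.22). Sirtuins, adipocyte, interferon, red blood cell and sinusoidal lists had 1 rise each, the clock list 1 fall, and the 14 proliferation genes none.

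From 2 weeks (n = 4) to 6 months (n = 6), 1203 genes were called, 636 up and 567 down. Kupffer markers rose in 9 of 10 (10 adjusted over the list alone; camera adjusted p = 6.4e-09), including C1qa (log2 1.04) and C1qb (log2 1.08), and acute phase genes in 4 of 14 (9 alone; adjusted p = 0.000484), including Fgb (log2 1.54). Fatty acid synthesis fell in 4 of 20 (8 alone; adjusted p = 0.000102), including Scd (463 ± 904 against 14895 ± 8383, log2 -6.55, SE 0.91, adjusted p = 0.000466), and cholesterol synthesis rose in 5 of 25 (8 alone; adjusted p = 0.000102). Also called were the lists of lymphocyte and neutrophil markers (2 rises of 10, 5 alone; adjusted p = 0.0105), p53 response (2 falls of 11, 4 falls and 1 rise alone; adjusted p = 0.0269) and miR-29 non-matrix targets (3 falls of 23, 4 alone; adjusted p = 0.04), the latter including the small GTPase gene Cdc42 (log2 -0.33). All 7 had an adjusted p = 0.503 with an estimated correlation. Hepatocyte markers had 3 rises and 1 fall of 9 (adjusted p = 0.136), the rises being Fgb, Apoa1 (log2 0.75) and Serpina1 (log2 0.62) and the fall Ttr (log2 -0.82). Xenobiotic genes had 3 rises and 1 fall of 10 (5 and 2 alone; adjusted p = 0.237), among them Abcc3 (log2 2.06), stress response genes 2 rises and 1 fall of 15 (adjusted p = 0.343), among them Chac1 (log2 1.19), and insulin genes 2 rises and 2 falls of 14 (3 and 2 alone; adjusted p = 0.504), among them Trib3 (log2 1.43) and Igf1 (log2 -0.58). The calls of Serpina1 and Lox ended in 7 and 6 of 10 omissions of a library. Those of Trib3, Igf1 and Chac1 ended without 2-week 1 or 2-week 2, that of Chac1 also without 6-month 2 or 6-month 5, that of Apoa1 without 2-week 4 and that of Ttr without 2-week 2 (adjusted p up to 0.119). Matrix targets had 1 fall, Lox (log2 -3.36; adjusted p for the list 0.636). Among genes with a mean of at least 50 counts the largest rises were those of Kcnma1 (log2 5.99), Foxq1 (log2 5.21), Crtac1 (log2 5.08) and Fst (log2 4.54). The count was 317 without 2-week 2, 474 without 2-week 1, 600 without 6-month 5, 712 without 2-week 4 and 749 without 6-month 6.

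The 3-month and 6-month changes share prediabetic controls. They correlated across genes with r = 0.87, against 0.48 for simulated unchanged groups, and their covariance was 0.325 against a simulated 0.0376. Rises shared by both numbered 810 (117 for independent lists) and shared falls 822 (120 for independent lists), with 0 genes called in opposite directions. With the controls split r was 0.75 and 0.54, with 235 and 247 shared rises and 262 and 277 shared falls. Median, mean and camera direction had the same sign in every called list of the RNA comparisons; among lists not called they differed for red blood cell markers (3 and 6 months, and LNA-29), sirtuins (6 months and LNA-29), hepatocyte markers (LNA-29), insulin genes (3 months), gluconeogenesis (6 months against 2 weeks), and acute phase, xenobiotic, clock and adipocyte genes at 2 weeks. Sirt1 was not among the genes tested in the rat table.

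**Figure D3:**
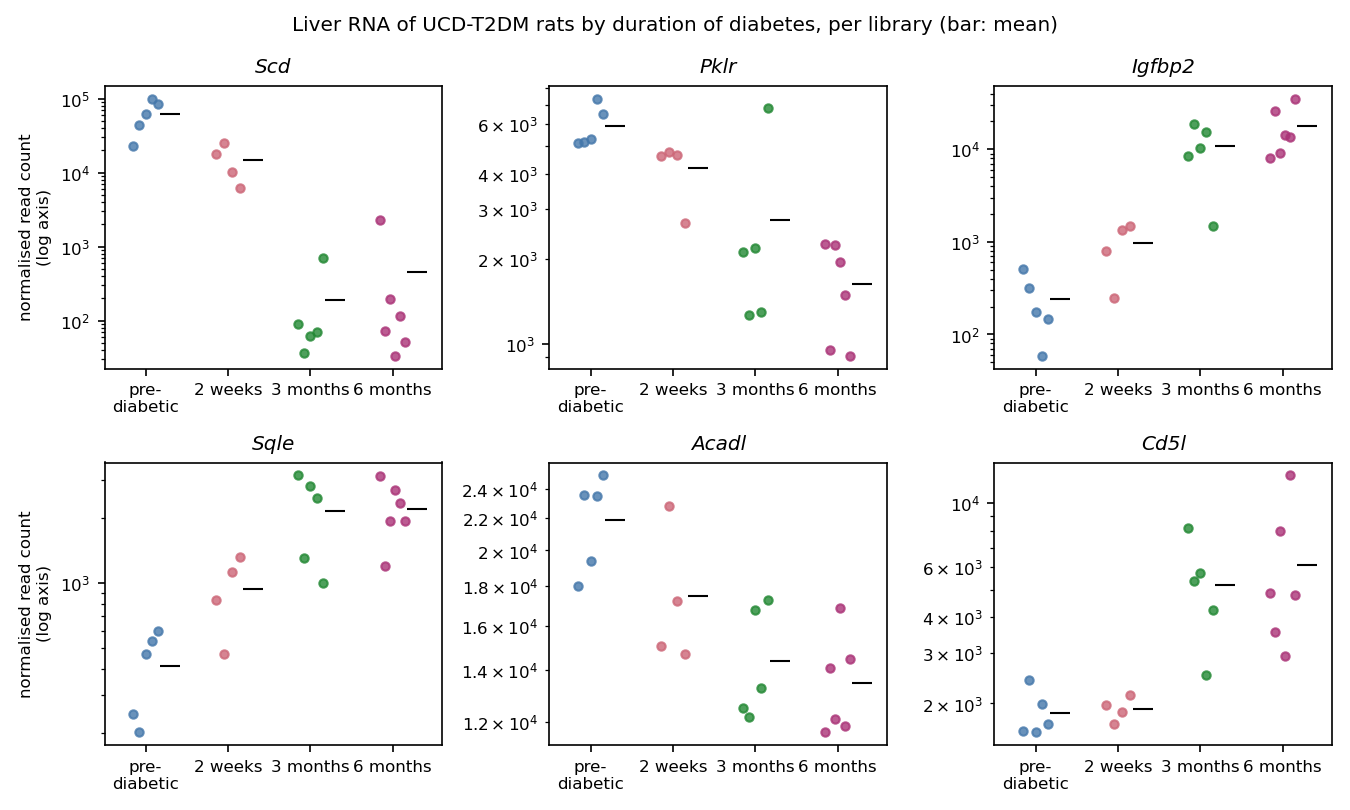
Normalised read counts of Scd, Pklr, Igfbp2, Sqle, Acadl and Cd5l in each UCD-T2DM RNA library on log axes, with bars for group means. Scd averaged 62742 counts before diabetes, 192 at 3 months and 463 at 6 months, and Igfbp2 averaged 242, 10849 and 17651.

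**Figure D4:**
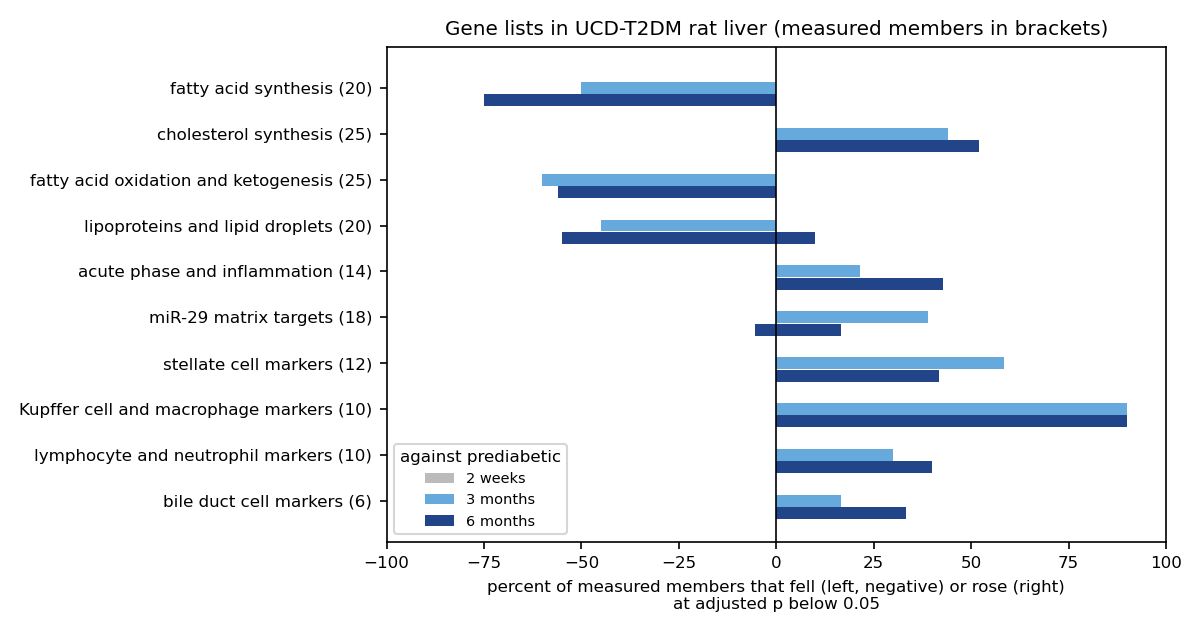
Percent of the measured members of each gene list called higher (right) or lower (left, drawn as negative) than in prediabetic UCD-T2DM rats at 2 weeks, 3 months and 6 months. No gene was called at 2 weeks; fatty acid synthesis had 10 falls at 3 months and 15 at 6 months, and Kupffer markers 9 rises at both.

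LNA-29 treatment (n = 5) against control mice (n = 6) asked which hepatic genes change when miR-29 is inhibited. Matrix genes on the fixed list of miR-29 targets rose: elastin, Eln (259 ± 57.8 against 72.2 ± 13.4, log2 1.82, SE 0.17, adjusted p = 0.000202), the collagen-binding protein gene Sparc (4250.4 ± 578 against 1770.1 ± 138, log2 1.26, SE 0.09, adjusted p = 2.0e-05), Col3a1 (log2 1.23; its call ended in 8 of 11 omissions of a library, adjusted p up to 0.0745) and Col4a5 (log2 0.91; adjusted p up to 0.0577 without treatment 3 or treatment 5). The DNA methyltransferases Dnmt3b (316 ± 54.3 against 124 ± 31.1, log2 1.36) and Dnmt3a (1482 ± 130.1 against 868 ± 71.4, log2 0.77) and the histone demethylase Kdm5b (log2 0.71) rose as well. The lipogenic desaturase Scd1 fell (11899.5 ± 6677 against 35867 ± 14847, log2 -1.65, SE 0.39, adjusted p = 0.0459), as did Cyp7a1, the rate-limiting enzyme of bile acid synthesis (11337 ± 3015 against 22293 ± 4025, SE of the log2 change 0.17, adjusted p = 0.0121). The deacetylase gene Sirt1, named in the study's title, was at 507 ± 28.6 against 599 ± 22.2 counts (log2 -0.24, SE 0.06, adjusted p = 0.0576, and 0.0373 to 0.183 over the alternatives) and was not called; 5 of 5 treated livers lay below every control, and it fell when adjusted over the list of 7 sirtuins alone.

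Of 14596 genes 355 were called, 229 up and 126 down. Rises outside the target lists included Pde10a (log2 1.67), Krt23 (log2 1.67), Wisp1 (log2 1.51), C1qtnf6 (log2 1.37) and Parp16 (log2 1.35), and falls Tmem267 (log2 -1.22) and Cyp2j9 (log2 -1.07). Matrix targets rose in 10 of 20 (13 adjusted over the list alone), and all 20 lay above controls with a median of 0.57 (camera adjusted p = 8.1e-15; adjusted p = 0.0557 with an estimated correlation). Non-matrix targets rose in 6 of 26 (7 rises and 3 falls alone; camera adjusted p = 0.0134; adjusted p = 0.0791 with an estimated correlation). Fatty acid synthesis had 1 fall of 22, Scd1 (2 alone; adjusted p = 0.413), and cholesterol synthesis, whose median was 0.26, 1 fall of 25, Tm7sf2 (log2 -0.46; adjusted p for the list 0.2).

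The clock list lay lower as a set with LNA-29 (camera adjusted p = 0.00409; adjusted p = 0.362 with an estimated correlation), although 0 of its 16 genes were called and 5 fell adjusted over the list alone; Per2 was at a log2 of -0.87 (adjusted p = 0.0662). Bile acid genes had 2 falls of 12 (2 rises and 3 falls alone; camera adjusted p = 0.305). The lists of lipoproteins, p53 response, hepatocyte markers and sinusoidal endothelium had 1 rise each, and the other lists tested with camera had 0 called genes. Adipocyte and pancreatic acinar markers, with 1 measured gene each, were not tested as lists; Fabp4 was at a log2 of 0.24 (adjusted p = 0.586) and the acinar elastase gene Cela2a rose (log2 1.37), a call that ended without treatment 1, 3 or 5. Stellate markers, the cells that make most hepatic matrix, differed by a mean log2 of 0.15 (exact permutation p = 0.108) where the matrix targets differed by 0.65 (exact permutation p = 0.00216). The Scd1 call ended in 9 of 11 omissions of a library (adjusted p up to 0.117), as did that of Tm7sf2, and Pde10a and Tmem267 ended in 7. The count of 355 was 120 without treatment 3, 125 without treatment 5, 144 without treatment 1, 164 without control 3, 165 without control 1, 186 without control 4, 194 without treatment 4, 224 without control 2 and 540 without treatment 2.

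**Figure D5:**
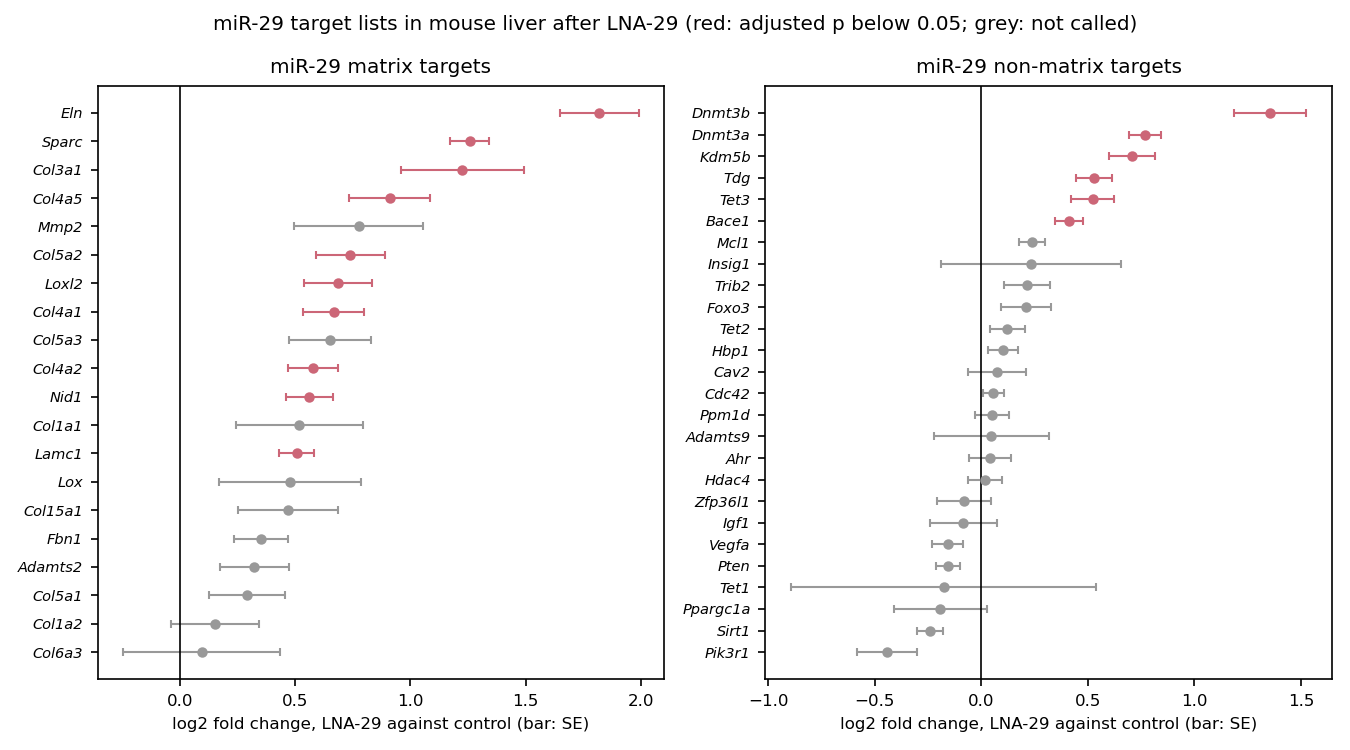
Log2 change and standard error of the tested members of the fixed miR-29 target lists with LNA-29 against control mice, red where called and grey otherwise. All 20 matrix targets lie above 0, and 6 of 26 non-matrix targets were called higher.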

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

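Which libraries stand apart was read from fixed statistics, and no explanation was tested for these results. A library was singled out when its gap to the nearest other library of its group, divided by the group's range, passed Dixon's limit. This happened in 26 of 537 group values, where chance gives about 1 in 20, or 26.85.

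Among rat miRNAs, 2-week 5 had 951 RPM of miR-181a-1-5p against 649 ± 38.8 in the other 2-week libraries (gap 0.668 of the range). Zucker obese 2 was high in miR-132-3p (66.3 RPM against 32.4 ± 2.08, gap 0.810) and miR-199a-5p (135 RPM against 64.0 ± 6.27, gap 0.772). Among mouse miRNAs, miR-802-5p in ob/ob 1 was at 1339 RPM against 1088 ± 34.5 (gap 0.711) and miR-107-3p in control 4 at 1032 against 794 ± 28.5 (gap 0.732). miR-375-3p in control 2 was low, at 8.65 against 21.2 ± 3.11 (gap 0.727). Streptozotocin 1 had 517 RPM of miR-29c-3p against 691 ± 11.9 (gap 0.881), and streptozotocin 3 had 2677 RPM of the imprinted miR-127-3p against 565 ± 69.7 (gap 0.856).

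In the rat RNA table libraries were singled out in the genes that follow. Lcn2 in 3-month 1 was at 35265 counts against 833 ± 365 (gap 0.734), Krt23 in 3-month 2 at 356 against 51.0 ± 15.3 (gap 0.730) and Cyp2b2 in 3-month 3 at 170 against 40.1 ± 7.92 (gap 0.729). 3-month 2 was low in Slc25a1 (2799.9 against 3867 ± 133, gap 0.804) and Igf1 (8453 against 12579 ± 618, gap 0.758). 3-month 1 was low in Slc37a4 (2524 against 6639 ± 573, gap 0.815), and 3-month 4 in Sesn2 (749.8 against 1285 ± 111, gap 0.717) and Plk2 (1315 against 2117 ± 129, gap 0.736). At 6 months Btg2 in 6-month 5 reached 22167 counts against 3786 ± 1145 (gap 0.662) and Atf4 in 6-month 6 reached 11045 against 9034 ± 261 (gap 0.705). AABR07048482.1 was listed at 0 in 6-month 6 against 62.9 ± 36.3 (gap 0.738), and LOC102548286 was at 86.3 in 6-month 1 against 0.394 ± 0.880 (gap 0.757).

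Prediabetic 2 had 7622 counts of Atf4 against 4675 ± 319 (gap 0.752) and was listed at 0 for LOC102548286 against 157 ± 44.4 (gap 0.870). Of the 2-week livers, 2-week 4 stood apart in Ppm1d (233 against 205 ± 1.76, gap 0.877) and in the glycolytic gene Pklr (2684 against 4688 ± 76.6, gap 0.946), and 2-week 1 was listed at 0 for Crtac1 against 1.33 ± 0.167 (gap 0.845). LNA control 3 was low in Kdm5b (792 against 979 ± 35.1, gap 0.653).

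Direct tests between disease groups that share controls were also passed. From 2 weeks to 3 months of UCD-T2DM diabetes 109 miRNA forms differed, between ob/ob and streptozotocin liver 65 forms differed, and from 2 weeks to 6 months 1203 genes differed. The miR-29 total differed between ob/ob and streptozotocin liver with an exact permutation p of 0.0317; leaving the lanes pooled, ob/ob liver was lower by -0.44 on the log2 scale.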

How the results depend on the processing

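The alternatives that sum forms over loci, average the miR-29 total over loci, leave the most abundant miRNA out of the form counts or drop 6 libraries in doubt were chosen after the data were seen. Of 3301 values of 347 named features under the alternatives, 3056 kept direction and side of the threshold, 227 lost and 9 gained the call, and 9 reversed; of 3485 values with 1 library left out the numbers were 3067, 402, 10 and 6. Of 239 values of 61 gene lists, 171 held, 58 lost and 9 gained the call, and 1 reversed. Tests of seed sites (no untranslated regions) and count models (whole reads not recovered) were not run. Unknown small RNA depth limits forms near the minimum mean. Unless the alternative tests fewer features or libraries, the cause was not tested.

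Without a minimum mean the counts were 15 (3 months against prediabetes), 249 (obese), 40 (ob/ob against streptozotocin), 1 (fish oil) and 212 (LNA-29). With a minimum mean of 100, and fewer features, they were 1 (3 months against prediabetes), 62 (3 months against 2 weeks), 61 (obese), 0 (BT2; limma, with 2 called and 73 at an unadjusted p under 0.05 in the full test), 69 (ob/ob), 11 (streptozotocin), 39 (between both) and 1 (fish oil). A pseudocount of 10 or no variance trend called 1 form with fish oil, and no trend called 195 genes with LNA-29. Rescaling gave 21 (3 months against prediabetes) and 1 (BT2), and leaving out the most abundant miRNA 28 (3 months against prediabetes), 108 (obese) and 1 (fish oil). The compared groups alone gave 0 (3 months against prediabetes; 5 called and 91 at an unadjusted p under 0.05 in the full test), 1 (BT2) and 15 (ob/ob against streptozotocin).

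Lane as a covariate gave 8 (BT2) and 98 (streptozotocin), and lane with a replicate block 1 (BT2), 95 (streptozotocin) and 43 (ob/ob against streptozotocin). Within lanes, where fewer libraries are tested, the counts were 39 and 29 (obese, lanes 1 and 2), 0 (BT2, lane 3), 32 and 59 (ob/ob, lanes 7 and 8), 16 (streptozotocin, lane 8), and 7 and 5 (ob/ob against streptozotocin). Without the libraries in doubt streptozotocin gave 74.

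Replicate numbers do not pair the libraries: correlations of same-numbered libraries fell between -0.589 and 0.684, and every comparison had a pair under 0.1. The replicate block gave 28 (3 months against prediabetes), 169 (3 months against 2 weeks), 71 (streptozotocin), 276 (6 months against 2 weeks) and 64 (LNA-29), and the miR-29 total in ob/ob liver had -0.44 with p = 0.0625 (exact permutation), the smallest that 5 pairs can give. With an estimated correlation 0 lists were called in all 5 RNA comparisons, against 8, 10, 9, 7 and 3, and with fry 0 at 2 weeks. In the other comparisons fry called the lists that camera called, apart from 3 groups of exceptions. These were acute phase and lymphocyte lists at 3 months, and the clock list with LNA-29 (fry adjusted p = 0.0556). From 2 weeks to 6 months they were cholesterol synthesis, lymphocyte and non-matrix lists. Both miR-29 target lists had a fry adjusted p of 0.000286 with LNA-29.

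The miR-29 total reversed in obese rats after rescaling (-0.029), with BT2 in lane 3 (-0.31) and without the libraries in doubt (-0.16), and in streptozotocin liver after rescaling (-0.18) and in lane 8 (-0.10). In ob/ob liver it was -0.10 in lane 7 and -0.68 in lane 8, where 2 against 3 libraries cannot give an exact p under 0.05, and it lost its side of 0.05 without the libraries in doubt (-0.40, exact permutation p = 0.0714). Members reversed as follows: in obese rats miR-29a-3p (-0.031) and miR-29c-1-3p (-0.062) after rescaling and miR-29c-1-3p in lane 1 (-0.25); with BT2 miR-29a-3p in lane 3 (-0.21) and without the libraries in doubt (-0.093); miR-29c-3p of ob/ob liver in lane 8 (0.021); miR-29a-3p of streptozotocin liver in lane 7 (0.054) and without the libraries in doubt (0.0084). Between both mouse models miR-375-3p was at 0.039 in lane 7. The non-matrix list at 3 months turned downward without the libraries in doubt (limma camera adjusted p = 0.462).

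With 1 library left out, counts ranged from 0 to 3 (3 months against prediabetes), 50 to 150 (3 months against 2 weeks), 114 to 188 (obese), 1 to 4 (BT2), 71 to 145 (ob/ob), 22 to 74 (streptozotocin), 19 to 80 (between both), 0 to 3 (fish oil), and in genes 0 to 3 (2 weeks), 1456 to 2389 (3 months), 1919 to 3567 (6 months), 317 to 1716 (6 months against 2 weeks) and 120 to 540 (LNA-29). With BT2 the 4 came without BT2 1, and 1 without BT2 2, 4 or 5 or vehicle 1, 2, 3 or 4; with fish oil 3 came without control 1 and 1 without control 2 or fish oil 3. miR-29 totals ranged from -0.29 to -0.076 (2 weeks; exact permutation p = 0.0357 without prediabetic 1), -0.035 to 0.18 (3 months), 0.17 to 0.33 (obese; exact permutation p = 0.0317 without obese 4 and 0.0397 without lean 5), -0.12 to 0.090 (BT2), -0.53 to -0.33 (ob/ob; exact permutation p of 0.0556 to 0.0714 without control 1, 2, 4 or 5), -0.029 to 0.075 (streptozotocin) and -0.66 to -0.25 (fish oil). Members that reversed ranged from -0.037 to 0.17 (miR-29a-3p) and -0.064 to 0.15 (miR-29c-1-3p) at 3 months, -0.049 to 0.13 (miR-29a-3p, BT2), -0.17 to 0.052 (miR-29c-3p, ob/ob) and -0.076 to 0.040 (miR-29a-3p, streptozotocin). Sirt1 with LNA-29 had adjusted p from 0.0373 (minimum mean of 100) to 0.183 over the alternatives, and 0.0439 without treatment 2.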

Other observations

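The tests of read composition and lane in Zucker rats, of Kupffer against endothelial markers, and of matrix targets against stellate markers were chosen only after the results were seen; the remaining tests were set beforehand.

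Beyond the comparisons described, rises of miR-34a-5p, miR-802-5p and miR-802-3p occurred in obese Zucker rats, ob/ob mice and streptozotocin-diabetic mice. Of 239 forms tested in both the Zucker and the mouse table, 37 rose in obese Zucker rats and 32 in ob/ob mice after rescaling, and 10 rose in both, against 4.95 for independent lists (Fisher exact p = 0.0154): miR-34a-5p, miR-802-5p, miR-802-3p, miR-103-3p, miR-221-3p, miR-222-3p, miR-148b-5p, miR-152-3p, miR-301a-3p and miR-322-3p. As deposited the number was 25 against 14.6 (Fisher exact p = 0.000297). Zucker and streptozotocin rises shared 3, against 1.55 (Fisher exact p = 0.189). Falls shared by obese Zucker rats and ob/ob mice numbered 8 after rescaling, against 4.84 for independent lists (Fisher exact p = 0.111), and 1 as deposited, against 0.762 (Fisher exact p = 0.558). For rises alone, the Fisher test (exact p = 0.0154) goes with a response common to both obese models, but it assumes independent forms. The tables also differ in composition: miR-122-5p held 2.38% to 6.36% of reads in mice and 38.1% to 55.2% in Zucker rats. Vehicle-treated Zucker fatty rats, whose miR-802-5p overlapped that of lean liver, did not enter this test.

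More miR-29 activity in diabetic rats would place the genes raised by LNA-29 lower, and camera did not call them lower: of 186 such genes measured, 16 rose and 18 fell at 3 months (limma camera adjusted p = 0.505, median -0.04) and 17 rose and 26 fell at 6 months (limma camera adjusted p = 0.440, median -0.04). Because the set's genes went both ways and the p exceeds 0.05, more miR-29 activity in some of them is left open. In the 6 rats measured in both UCD-T2DM tables, the miR-29 total and the mean log2 of matrix targets gave r = -0.45 (exact permutation p = 0.347) and rho = -0.54 (exact permutation p = 0.297). These rats were pooled from the prediabetic, 2-week and 3-month groups, so differences between groups enter r. Without the 2 rats farthest from the median r was 0.11, and with 4 relations computed the adjusted p was 0.463. The single pancreatic acinar gene tested in LNA-29 mice, Cela2a, rose (41.2 counts against 16.0, log2 1.37, adjusted p = 0.0221), and the other acinar genes were between 0 and 1.02 counts in every library.

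More miRNA forms rose than fell in obese Zucker rats. A lower share of the most abundant miRNA, miR-122-5p, would raise the others in RPM, by a log2 of 0.20 here, where the median form differed by 0.27. Per 1000000 reads other than miR-122-5p, 75.9% of called forms were rises (70.2% to 84.4% with 1 library left out), against 92.0% as deposited, and the median was 0.10, so how much of the imbalance this share accounts for stays open. Lean and obese libraries were spread alike over the lanes, 2 each in lanes 1 and 2 and 1 each in lane 3. A shift between lanes can therefore not account for the imbalance. With that balance a lane covariate could remove few calls, and 99.4% of the called forms were also called with it. The leptin receptor mutation and obesity stay open as well, untested.

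Kupffer cell and macrophage markers rose at 6 months of UCD-T2DM diabetes. A lower share of hepatocytes would raise the markers of every other cell type alike. Kupffer markers rose by 0.88 more than sinusoidal endothelial markers (SE 0.25, exact permutation p = 0.013, uncorrected). Sinusoidal markers also rose less than lymphocyte and neutrophil markers (-0.75, exact permutation p = 0.0281). Kupffer markers differed in their rise by -0.30 from bile duct markers (exact permutation p = 0.595). From lymphocyte and neutrophil markers they differed by 0.13 (exact permutation p = 0.578). Only pairs with the sinusoidal list went against a lower hepatocyte share, so it stays open. The library in doubt, the control prediabetic 2, is not needed for the rise, since all 10 measured members were called without it. It had the highest Cd5l of the prediabetic livers (2412 counts), so leaving it out could hardly weaken the rise. The list was not counted again without single 6-month livers. More macrophages, or more transcript per macrophage, may account for the rise; stellate markers differed from Kupffer markers by 0.49 (exact permutation p = 0.158), so a rise of several cell types stays open.

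Matrix targets of miR-29 rose with LNA-29. More stellate cells would raise stellate markers as much, but matrix targets rose by 0.51 more (SE 0.12, exact permutation p = 0.00216). The number of called members rested in part on single livers: it fell to 3 without treatment 3 and to 4 without treatment 5, and was 7 to 10 otherwise. Relief of repression by miR-29 may account for the rise, with the time of collection untested.

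The fall of Scd1 with LNA-29 may reflect the time of collection or feeding. Within the groups Scd1 followed the mean of the clock list with r = 0.65 (permutation p = 0.0335) and rho = 0.69 (permutation p = 0.0224). The relation did not pass correction over 4 relations (adjusted p = 0.134), and r was 0.46 without the 2 farthest libraries. Scd1 gave r = 0.11 with Dbp (permutation p = 0.733) and 0.48 with Per2 (permutation p = 0.139).

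Other splits of the same libraries, 100 drawn per comparison or all where fewer exist, were fitted to ask whether chance alone gives such counts. Only the real split of 100 reached the real count in obese rats (163, highest other 140) and with BT2 (2, highest other 0). The same held for ob/ob (119, 65), streptozotocin (43, 41), 3 months (2248, 557) and 6 months (2875, 2016). It also held for 6 months against 2 weeks (1203, 645) and for LNA-29 (355, 36). These ranks were not corrected over the comparisons, so they make chance less likely in these comparisons without excluding it. The margin was small with streptozotocin (43 against 41) and BT2 (2 against 0). For 3 months against 2 weeks, 2 of 84 splits reached 109. The highest other called 166 by setting 2-week 1, 3 and 5 apart. A split that ignores duration can thus give a larger count, and chance stays open there. Between ob/ob and streptozotocin mice 2 of 100 splits reached 65, and the highest other, at 84, set lane 7 against lane 8; within lanes 7 and 5 forms were called, and 75 with lane as a covariate. At 2 weeks no real count exceeded 0, so all 84 splits of small RNA and all 100 of RNA reached it. A split of 2-week 2, 4 and 6 with the prediabetic libraries against 2-week 1, 3 and 5 called 161 forms, which points to a structure within the 2-week group. miR-122-5p held 52.8% to 55.1% of reads in 2-week 1, 3 and 5 and 46.3% to 50.2% in 2-week 2, 4 and 6. Whether this share accounts for the split was not tested. The highest other RNA split called 2 genes. Only 10 splits exist for 3 months against prediabetes (1 reached 5; highest other 0) and for fish oil (10 reached 0; highest other 0), too few for a share under 0.05.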
